A study of Oryctolagus cuniculus with 18 samples.

How the data were processed

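Gene expression was measured in pools of rabbit (Oryctolagus cuniculus) embryos that developed in vivo, at the 4-cell, early morula (called morula below) and expanded blastocyst stages. There were 9 pools, 3 per stage, and each gave 2 arrays, so 18 arrays in all. Per the labels' protocols, RNA was extracted from batches of embryos, treated with DNase and amplified either by in vitro transcription into antisense RNA (aRNA) or by PCR in 2 rounds of 18 cycles. Amplified material was then labelled with 33P and hybridised. Each group of 3 arrays (a stage and an amplification) is named by stage, amplification and pool number. The labels describe the pools as separate batches of embryos from 2 to 7 females, so the pool was taken as the replicate and the 2 arrays of a pool as technical measurements of it.

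The deposited array tables hold 1 spot intensity per row on a linear scale, quantified by the authors with AGScan at a constant spot diameter, per the file headers. They have no background column. Each table has 2304 spots in 16 blocks of 12 rows and 12 columns. A deposited quality column holds 0 or 1 per spot, and its meaning is not given in the sources used here. The deposited series table holds a score per spot name. Over the clones spotted once, its columns correlated with the log2 raw intensity of their own array at r of at least 1.00 after rounding, with column medians from -0.21 to -0.05 and SDs of 0.94, so its direction and centring follow from the arrays. The log base and the reason for its SD stay unknown, and how the authors made the score is not given in the sources used here. Its values served as an alternative. It has 0 columns of other samples.

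Names with the prefixes lcal, lcao, lcap and lcaq (2052 names on 2087 spots, 2036 of them spotted once) were taken as clones. Of the other 217 spots, with the prefixes LMAA, XVAB and XWAB, 208 lie at 13 positions that such spots hold in every block and 9 lie elsewhere. Their role is not given in the sources used here, and they entered the background correction but no test of clones. The files do not pair clone IDs with genes. Gene lists fixed before the data were examined could therefore not be tested, and clones are given by ID.

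Intensities were corrected with limma's normexp method (offset 50) over all spots of an array and log2 transformed. Clone spots were quantile normalized within each amplification, and spots of a clone averaged. This gives the arrays of all stages the same distribution, so rises and falls between stages are relative to the other clones. The means of each pool's 2 arrays were fitted with limma (lmFit and eBayes) over all 9 pools, which share an estimate of the spread. A clone was called at a Benjamini-Hochberg adjusted p under 0.05, in an F test over the 3 stages and in each of 3 contrasts between stages, and the same was done on the 9 arrays of each amplification alone. For PCR against aRNA, all 18 arrays were quantile normalized together and the 9 differences within pools were tested with limma, as a mean over stages and, for the interaction, as an F test over stages. Errors given as SE come from these fits and errors given as SD from the 3 pools of a stage. Versions were R 4.3.3, limma 3.58.1, matplotlib 3.10.9 and pandas 2.3.3.

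The rule for named items, written before the data were examined, took genes with the largest rise and fall among those called with the same sign in both amplifications. For probes without gene names it allowed at most 2 IDs per direction, and that part was used. Where a clone lay above the 95th percentile of the XWAB spots on none or 1 of the 6 arrays of a stage, or on some but not all of the 9 arrays of an amplification, its fold is given as a lower bound. The bound sets the mean of the brighter group against the mean, over the pools of the dimmer group, of the higher of the clone's own value and the lowest value on that array among clone spots over that percentile. This level was chosen here, since the files mark no spots as above background.

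Per the deposited intensities, the median over clone spots ran from 28 to 386 per array, and 10.1% to 25.2% of clone spots lay above the XWAB percentile. The number of arrays limits the precision. Tested on simulated data (2052 clones, 200 of them changed, 5 runs), the F test recovered 68.4% of changes of 1 and 99% of changes of 2 on the log2 scale. The morula versus 4-cell contrast recovered 63.4% and 98.4%, and the blastocyst versus morula contrast 67.8% and 99.2%. PCR against aRNA recovered 95.2% and 100%. The interaction recovered only 10.4% of changes of 1 and 86.4% of changes of 2. False calls made up 4.6% to 5.52% of the calls in these comparisons. The simulated noise was independent between clones and had the same SD at every stage, and stage changes were placed in the morula pools only. No array code effect or signal from neighbouring spots was simulated. For PCR against aRNA and the interaction, changes were added after normalization within each amplification, unlike in the reported fits. These rates may therefore not hold for the real arrays.

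The labels carry an array code whose number (4, 5 or 6) is shared by 1 pool of each stage, and it was used as a possible batch. The last digit of the code goes with the amplification, so any effect of it cannot be told apart from amplification. Alternatives planned before the data were examined were median centring, quantile normalization over all 18 arrays, no background correction, the series table, leaving out the dimmest 25% of clones, a fit to all 18 arrays with the pool as a random block, array weights, the replicate number or the array code as a block, fits to only the stages compared, and leaving out each pool. Alternatives added after seeing the data were restriction to clones with quality value 1 on at least 3 arrays, leaving out the pools of each array code, and restriction to clones with no adjacent spot at 4 times their mean raw intensity or more.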

Results

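Transcript levels were followed through rabbit preimplantation development in vivo, at 32 h (4-cell embryos), 58 h (early morulae) and 90 h post coitum (expanded blastocysts), with 1 blastocyst pool collected at 96 h. Each stage had 3 pools, of 16 to 60 embryos where the labels give a number, and each pool was hybridised to nylon cDNA filters after aRNA and after PCR amplification. Of the 2052 clones measured, 1017 carry the name prefix lcao and 1017 the prefix lcap. The files do not say what the prefixes stand for and do not pair clone IDs with genes. Median raw clone intensity per array ran from 29 to 122 in 4-cell, 68 to 350 in morula and 28 to 386 in blastocyst arrays.

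The stages were well separated. Pools of the same stage correlated across clones at r of 0.82 to 0.88 in 4-cell embryos, 0.88 to 0.97 in morulae and 0.93 to 0.99 in blastocysts. Pools of different stages correlated at a median r of 0.70 between 4-cell and morula, 0.69 between morula and blastocyst and 0.51 between 4-cell and blastocyst; clones are not independent replicates. The first principal component held 52.8% and the second 24.4% of the variance. The median SD of a clone among the 3 pools was 0.31 at the 4-cell stage, 0.23 in morulae and 0.18 in blastocysts (log2).

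**Figure D1:**
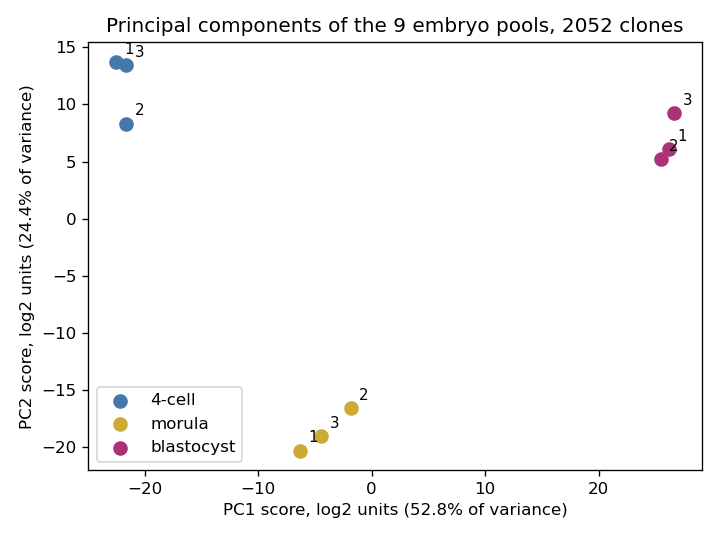
Scores of the 9 embryo pools on the first (x axis, 52.8% of variance) and second (y axis, 24.4%) principal components of normalized log2 intensity over 2052 clones; each point is a pool, numbered by replicate and coloured by stage. The 3 pools of each stage lie together and apart from the other stages.

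The first question was which transcripts change in level among the stages. A total of 708 of 2052 clones (34.5%) differed among the 3 stages by limma's F test. Of these, 254 were highest in 4-cell embryos, 221 in morulae and 233 in blastocysts, while 287 were lowest in 4-cell embryos, 153 in morulae and 268 in blastocysts. In their highest stage, 211 of the 708 lay above the 95th percentile of the XWAB spots on all 6 arrays and 160 on none. Of the 708, 340 had an adjacent spot at 4 times their mean raw intensity or more, and 271 of these (79.7%) changed in the direction of the brightest such spot, against 49.2% over all spots that bright. Under median centring 389 clones differed and with array weights 1065, and without the pools of array code 5 or 6 the counts were 391 and 428. Each array code holds 1 pool per stage, so no test could be made within it; with the code as a block 753 clones differed among stages, 501 between 4-cell and morula, 349 between morula and blastocyst and 626 between 4-cell and blastocyst.

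Between the 4-cell stage and the morula, 437 clones changed in level relative to the other clones: 241 rose and 196 fell. The median size of these changes was 1.25 on the log2 scale, 301 exceeded 2-fold and 57 exceeded 4-fold (39 up, 18 down). The largest rises were in lcao0031h07, from a mean of 7.67 ± 0.30 to 11.54 ± 0.35 (log2, SD, n = 3; at least 7.12-fold, change 3.86 ± 0.26 SE, adjusted p = 2.13e-06), and in lcao0024a04 (at least 5.41-fold, 3.65 ± 0.34 SE, adjusted p = 2.45e-05). Each was above the XWAB percentile on 1 of 6 4-cell arrays and on 6 of 6 morula arrays. The largest falls were in lcao0043e06, which changed by -4.22 ± 0.21 (SE, adjusted p = 3.73e-07) and was at least 8.85-fold lower in morulae, and in lcao0030h12 (-3.57 ± 0.34 SE, at least 5.76-fold lower, adjusted p = 2.52e-05, above the percentile on 1 of 6 morula arrays).

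The direction of change differed between the groups of clones that share a prefix, a pattern chosen for testing after the data were seen. Among lcap clones 158 rose and 66 fell from 4-cell to morula, whereas among lcao clones 82 rose and 128 fell (Fisher's exact test, two-sided, over clones, adjusted p = 7.28e-07 for the rises and 6.14e-06 for the falls, 7 tests). Fisher's test counts clones as independent although all were measured in the same pools, so its p-values do not reflect variation between pools. The upward shift of lcap clones relative to the other clones passed camera with its preset correlation (adjusted p = 7.42e-05) and with an estimated correlation (adjusted p = 0.0049). Over all clones tested, 71.7% changed with the same sign on the aRNA and on the PCR arrays, against 49.0% to 61.9% (median 54.5%) between groups made of 1 pool of each stage, and in 36.7% the pools of the stages did not overlap, which chance gives for 10%. Median centring in place of quantile normalization left 155 calls, of which 129 rose (83.2%, against 55.1%). The count was 232 (144 up, 88 down) without the pools of array code 5 and 243 (129 up, 114 down) without those of code 6. It was 263 (167 up, 96 down) among clones with no adjacent spot at 4 times their intensity or more.

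Between morula and blastocyst, 330 clones changed, 165 in each direction. Fitted on only the 2 stages compared, 401 clones changed (191 up, 210 down). The same kind of fit gave 340 between 4-cell and morula (200 up, 140 down). Which step had more calls therefore depended on the processing. The order was also reversed with all stages in the fit under median centring (155 from 4-cell to morula, 199 from morula to blastocyst) and array weights (528 and 793). The median size was 1.25 (log2), and 68 changes exceeded 4-fold (46 up, 22 down). The largest rises were in lcao0026e02, from 6.77 ± 0.80 to 13.00 ± 0.35 (log2, SD, n = 3; at least 23.5-fold, change 6.24 ± 0.35 SE, adjusted p = 1.82e-07), and lcao0023g07 (at least 32.3-fold, 5.96 ± 0.23 SE, adjusted p = 1.73e-08). Both were above the XWAB percentile on 6 of 6 blastocyst arrays and 1 of 6 morula arrays. The largest falls were in lcap0011e04, which changed by -4.62 ± 0.34 (SE, adjusted p = 1.21e-06), and lcap0002b10, which changed by -4.20 ± 0.27 (SE, adjusted p = 4.39e-07); blastocyst levels were at least 13.3-fold and 7.04-fold lower.

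The prefix groups moved the opposite way at this step: 52 lcap clones rose and 137 fell, against 112 and 28 lcao clones (Fisher's exact test, adjusted p = 2.85e-06 and 5.62e-19). Here too Fisher's test took clones as independent, so its p-values do not reflect variation between pools. Camera gave the fall of lcap clones relative to the other clones an adjusted p of 3.91e-07 with the preset and 0.00238 with an estimated correlation. Over all clones tested, 73.1% had the same sign in both amplifications, and in 39.4% the pools did not overlap, against 10% by chance. With median centring 199 clones changed, 132 up and 67 down (66.3% up, against 50%). Array weights gave 793 (345 up, 448 down), leaving out the pools of array code 5 gave 181 (98 up, 83 down), leaving out those of code 6 gave 181 (104 up, 77 down), and clones with no brighter neighbouring spot gave 177 (59 up, 118 down).

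**Figure D2:**
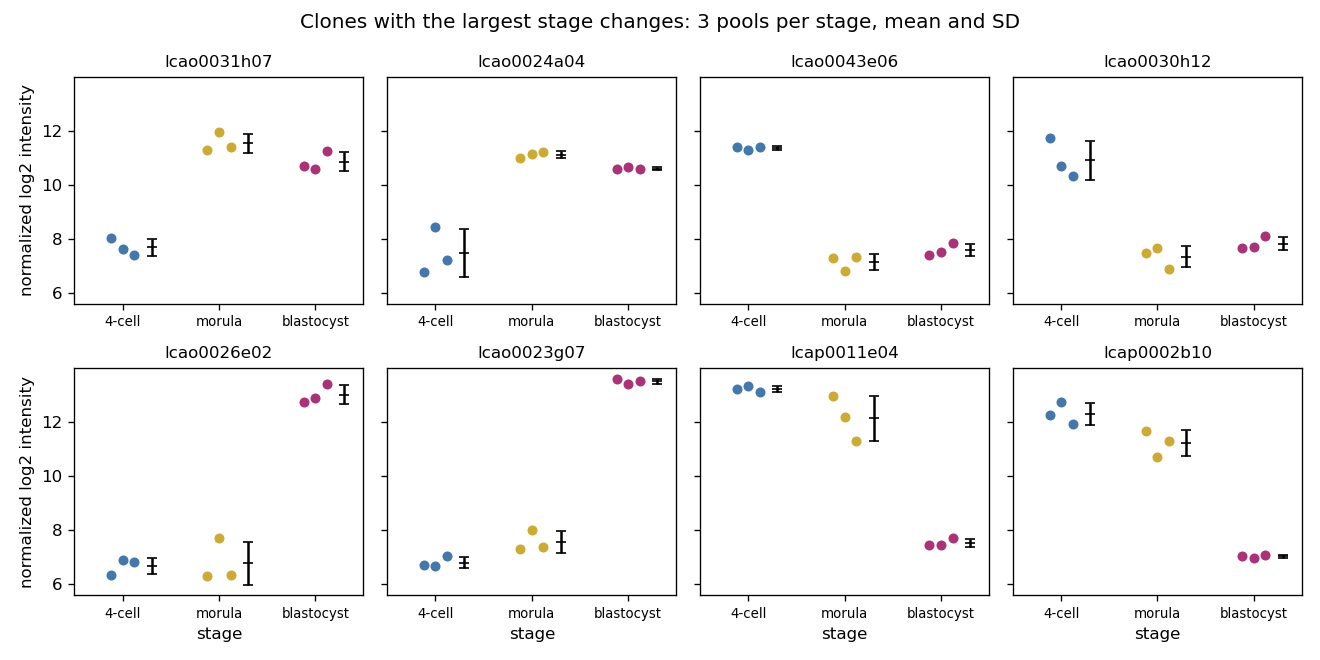
Normalized log2 intensity (y axis) by stage (x axis) of the 8 clones with the largest rises and falls; points are the 3 pools of a stage and bars the mean and SD. The blastocyst pools of lcao0026e02 and lcao0023g07 lie above all of their other pools, and those of lcap0011e04 and lcap0002b10 below.

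From the first to the last stage, 592 clones changed, 301 up and 291 down, with a median size of 1.28 (log2) and 115 beyond 4-fold (73 up, 42 down). The clones at the top were those of the step to the blastocyst: lcao0023g07 rose by 6.71 ± 0.23 (SE, adjusted p = 4.35e-09) and lcao0026e02 by 6.33 ± 0.35 (SE, adjusted p = 9.08e-08), at least 29-fold and 20.5-fold. The lcap0011e04 signal changed by -5.70 ± 0.34 (SE, adjusted p = 1.56e-07) and lcap0002b10 by -5.29 ± 0.27 (SE, adjusted p = 6.47e-08), at least 28.1-fold and 14.9-fold lower. Of lcap clones 120 rose and 136 fell, and of lcao clones 180 rose and 153 fell (Fisher's exact test, adjusted p = 0.000304 and 0.362), while camera gave lcap clones an adjusted p of 0.615 with the preset and 0.58 with an estimated correlation. The Fisher p-values again take clones as independent, and camera called no shift of lcap clones with either correlation. Over all clones tested, 74.9% had the same sign in both amplifications and 44.5% had pools that did not overlap, against 10% by chance. Median centring gave 312 calls, of which 246 rose (78.8%, against 50.8%), and leaving out the pools of array code 5 gave 351 (199 up, 152 down). Clones with no adjacent spot at 4 times their intensity or more gave 299 (151 up, 148 down).

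**Figure D3:**
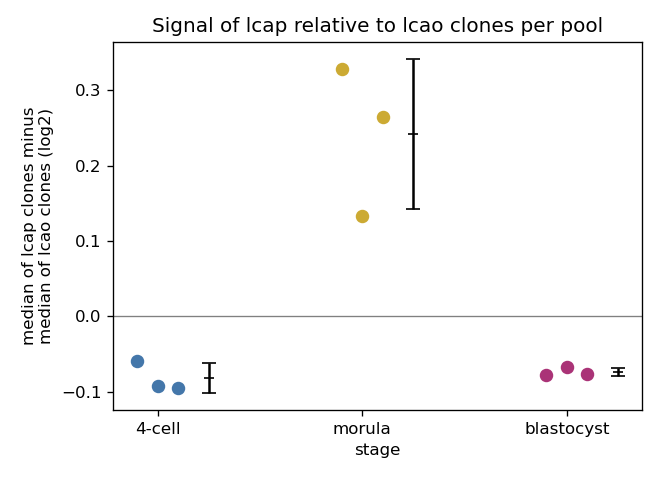
Median normalized log2 intensity of the 1017 lcap clones minus that of the 1017 lcao clones (y axis) in each pool, by stage (x axis), with the mean and SD of 3 pools. The difference was 0.24 ± 0.10 in morulae, against -0.08 ± 0.02 at the 4-cell stage and -0.07 ± 0.01 in blastocysts.

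Each amplification alone showed the stage differences too. On aRNA arrays 580 clones differed among stages, with 200 up and 136 down from 4-cell to morula, 133 up and 136 down from morula to blastocyst, and 260 up and 222 down from 4-cell to blastocyst. On PCR arrays 442 differed, with 141 up and 114 down, 113 up and 76 down, and 229 up and 168 down in the same order. Clones called up by both numbered 104, 87 and 170, clones called down by both 61, 58 and 118, and 0 were called in opposite directions. The overlap of independent lists would be 13.7, 7.32 and 29 up and 7.56, 5.04 and 18.2 down, but both amplifications measured the same pools. On aRNA arrays the morula to blastocyst count was 169 (97 up, 72 down) without morula array 1, 179 (94 up, 85 down) without morula array 3, 173 (96 up, 77 down) without blastocyst array 1 and 162 (92 up, 70 down) without blastocyst array 2, and the 4-cell to morula count was 221 (136 up, 85 down) without morula array 1. On PCR arrays the morula to blastocyst count was 115 (74 up, 41 down) without blastocyst array 1 and 119 (75 up, 44 down) without array 3. Across clones the changes on aRNA and PCR arrays correlated at r of 0.76, 0.86 and 0.86.

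Median centring raised the share of rises here as well. On aRNA arrays 119 rose and 22 fell from 4-cell to morula (84.4% up, against 59.5%), 114 and 62 from morula to blastocyst (64.8%, against 49.4%), and 192 and 52 from 4-cell to blastocyst (78.7%, against 53.9%). On PCR arrays 80 rose and 10 fell (88.9%, against 55.3%), 91 and 35 (72.2%, against 59.8%), and 176 and 28 (86.3%, against 57.7%).

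**Figure D4:**
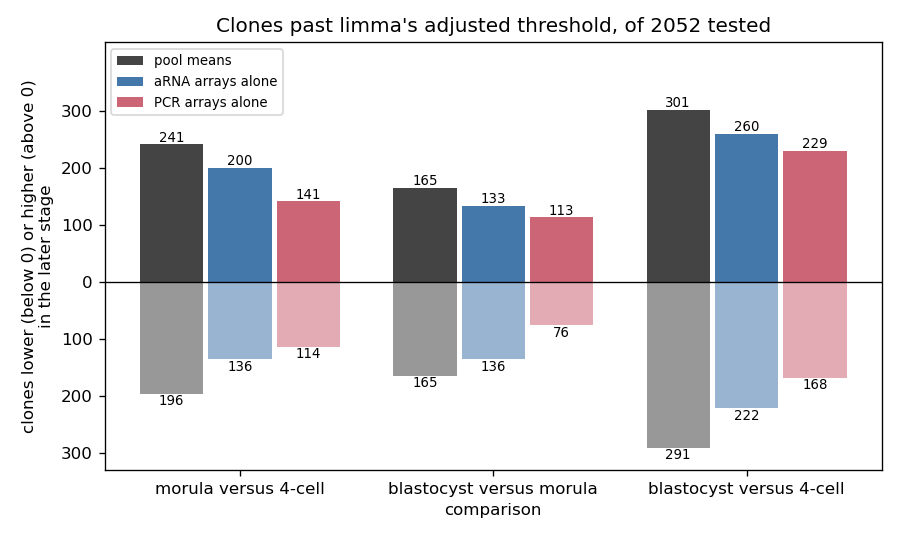
Number of clones past limma's adjusted threshold (y axis; higher in the later stage above 0, lower below 0) in each comparison of stages (x axis), for the pool means and for each amplification alone. Pool means gave 241 up and 196 down, 165 and 165, and 301 and 291 clones.

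The amplifications were also set against each other within pools. The signal of 394 clones differed between PCR and aRNA, higher on PCR arrays in 190 and lower in 204, and 104 differed by over 2-fold. The largest were lcap0025b03 (3.46 ± 0.26 SE log2 higher on PCR arrays, at least 9.38-fold, adjusted p = 5.84e-06) and lcao0049b02 (3.11 ± 0.28 SE, at least 6.46-fold, adjusted p = 2.5e-05) on one side, and lcao0044f06 (-2.12 ± 0.23 SE, 4.33-fold, adjusted p = 8.64e-05) and lcao0040b06 (-2.08 ± 0.28 SE, at least 3.61-fold lower, adjusted p = 0.000386) on the other, each with the same sign in 9 of 9 pools. The first, second and last of these were above the XWAB percentile on 5, 5 and 4 of the 9 arrays of their dimmer amplification. Of the 394, 188 had the same sign in all 9 pools. Of lcap clones 74 were higher and 122 lower on PCR arrays, and of lcao clones 110 were higher and 81 lower. With quantile normalization within each amplification, 1248 clones differed, 54 higher and 1194 lower on PCR arrays (4.33% higher, against 48.2%).

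By limma's F test on the differences within pools, 0 clones had a stage difference that depended on the amplification, with 148 at an unadjusted p under 0.05, where chance gives 103. The lowest adjusted p was 0.0774, and the median SE of 0.41 (log2) limits what could be detected. Leaving out 4-cell pool 2 gave 4 clones and median centring gave 1.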

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

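The tests on the neighbouring spots of the 2 clones here were chosen after the values of these clones had been seen, with bounds set before the neighbours' values were. For 2 clones the change from 4-cell to blastocyst differed between the amplifications by limma, although the F test over stages called 0. The change of lcao0019c03 was -2.51 on aRNA and -0.36 on PCR arrays, a difference of 2.15 ± 0.33 (SE, log2, adjusted p = 0.0343). This clone was above the XWAB percentile on 3 of 6 4-cell arrays and on 0 of 6 blastocyst arrays, so its changes may be understated. For lcap0017g10 the change was 1.48 on aRNA and -0.81 on PCR arrays, a difference of -2.28 ± 0.35 (SE, adjusted p = 0.0343).

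Signal spreading from brighter adjacent spots is a candidate explanation for these differences. The brightest neighbour of lcao0019c03 was 16.1 times as bright, and this spot, lcap0025b03, was itself 3.46 log2 higher on PCR arrays. Its own difference in stage change was -0.87 ± 0.63 (SE), opposite in sign to that of the clone, but spread from it on PCR arrays could mask a fall of the clone there whatever its own stage change, so this stays open. The brightest neighbour of lcap0017g10 was 13.4 times as bright and differed by -0.89 ± 0.40 (SE), in the direction of the clone but smaller, so it stays open there too. No biological explanation was tested, since the design gives none for a difference between amplifications of the same pools.

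Splits of the pools say nothing here: with a real count of 0 in the F test, 100 of 100 splits gave at least as many by construction (highest other 0).

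Among the 80 names with the prefixes LMAA, XVAB and XWAB, which entered no comparison of clones, 6 differed among stages by limma's F test, all with the prefix XWAB.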

How the results depend on the processing

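Leaving out the pools of an array code and the restrictions by quality value and neighbouring spots were chosen after seeing the data; the other alternatives, the array code as a block included, were planned. All 16 results of named clones kept their direction and their side of the threshold in all 348 recalculations, and 202 of 236 recalculated counts stayed within 1.5 times the reported count. In some settings, such as the block fits and the restrictions on clones, the change of a clone was the same by construction. Only its adjusted p could move there, and the named clones were picked for the largest changes. The gene lists and the genes named with them were not run, since clones have no gene names. The cause of a moved count was not tested. In some settings fewer samples or clones entered by construction.

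Median centring gave 389 clones differing among stages, 155 morula versus 4-cell, 199 blastocyst versus morula and 312 blastocyst versus 4-cell, of which 379, 151, 196 and 299 were calls of the reported fit. It gave 317, 141, 176 and 244 on aRNA arrays alone, 246, 90 and 204 (any stage, morula versus 4-cell, blastocyst versus 4-cell) on PCR arrays alone, and 1 clone with a stage difference that depended on amplification. Array weights (0.301 to 5.07) gave 1065 and, for blastocyst versus morula, 793. Quantile normalization within each amplification, which sets each amplification to its own distribution, gave 1248 for PCR versus aRNA. With fewer samples, leaving out the pools of array code 5 gave 391, 232, 181 and 351, and of code 6 gave 428, 243 and 181 (blastocyst versus 4-cell 396); leaving out the dim code 4 gave 780. With fewer clones, those with no adjacent spot at 4 times their intensity or more gave 377 of 728, 263, 177 and 299. Those with quality value 1 on at least 3 arrays gave 512, 363 (224 up, 139 down), 251 (98 up, 153 down, so 39% up, against 50%) and 400 (206 up, 194 down). Without the dimmest 25% of clones 690 differed among stages.

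The replicate numbers did not pair the pools: same-numbered pools of different stages had correlations of deviations from -0.20 to 0.20, 3 of 9 over 0.1, and 2 of 9 pools correlated best with their own number. With the replicate block the counts were 663, 437, 298 and 579 on pool means, 554, 328, 247 and 483 on aRNA arrays and 403, 231, 167 and 391 on PCR arrays. Pools sharing an array code had correlations from -0.01 to 0.24, 5 of 9 over 0.1, among them the 3 pairs of code 4 (0.11 to 0.24); with the code as a block the counts were 753, 501, 349 and 626. For PCR versus aRNA, where the pool is the block, the unpaired fit gave 353.

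Leaving out each pool gave 581 to 731 clones differing among stages, 331 to 444 morula versus 4-cell, 233 to 360 blastocyst versus morula and 475 to 647 blastocyst versus 4-cell. On aRNA arrays the ranges were 435 to 599, 221 to 368, 162 to 311 and 340 to 499, and on PCR arrays 316 to 525, 174 to 283, 115 to 216 and 278 to 470. The arrays that moved a count over 1.5 times were morula aRNA 1 (221 morula versus 4-cell; 169 blastocyst versus morula), and, for blastocyst versus morula, morula aRNA 3 (179), blastocyst aRNA 1 (173) and 2 (162), and blastocyst PCR 1 (115) and 3 (119). PCR versus aRNA ranged from 274 to 452 and the dependence on amplification from 0 to 4 (4 without 4-cell pool 2).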

Other observations

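The tests on neighbouring spots and on the prefix groups were chosen after the pattern had been seen, with their bounds set before each was run. Exceptions were the test by direction for clones with no adjacent spot at 4 times their intensity and the matching on brightness, which were chosen after seeing the values. The tests by array code came after the data were seen. Clones of the largest changes were bright: none of the 12 named in the comparisons of stages and amplifications had an adjacent spot brighter than itself. Blastocyst pool 1, collected at 96 h, correlated with the 90 h pools at r of 0.99 and 0.94, and those with each other at 0.93, with no test. The LMAA spots, relative to the median clone, were dimmest on the code 4 array in each of 6 groups, at 0.62 to 3.73 log2 above it, against 2.60 to 5.53 on the other arrays.

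The count of clones differing among stages was set against other splits of the pools. Of 100 splits, the real one included, 1 reached it (real 708, highest other 176). This is the lowest share such a test can give, so it makes chance in how the pools were grouped unlikely but does not exclude it. The same held for aRNA arrays (1 of 100; 580 and 135), PCR arrays (1 of 100; 442 and 136) and PCR versus aRNA (1 of 100 swaps within pools; 394 and 168). Each contrast between stages has 10 splits, too few for a share under 0.05; 1 of 10 reached the real count of 437, 330 and 592, and the highest other was 0.

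Part of the stage differences may be signal spreading from brighter spots on the filter. For the 728 clones with no adjacent spot at 4 times their intensity this is argued against as the whole cause, since 50.5% were called, against 45.6% of all clones at matched brightness, and 58.2% of the called ones (exact 95% interval 52.9% to 63.2%) changed in the direction of their brightest adjacent spot. That interval lies above the 49.2% used below as the comparison for brighter neighbours, so spread as part of the cause stays open for the 728. Of the 340 called clones with an adjacent spot at 4 times their intensity or more, 79.7% changed in the direction of the brightest (exact 95% interval 75.0% to 83.8%). Over all spots as bright the share was 49.2%, below the whole interval, which points to spread as part of the cause for these clones. The share was 69.8% among clones with such a neighbour that were not called. Spread as the whole cause stays open for the 340, since 79.7% fell just under the 80% set as its mark. Across the 76 XWAB names the change from 4-cell to morula correlated with that of the neighbours at r = 0.18 (upper 95% bound 0.39), which does not decide for the 6 that changed. Uneven array brightness is argued against, since 679 clones differed with pool brightness as a covariate (624 shared with the 708). Of the 512 clones called morula versus 4-cell without the dim code 4 pools, 90.8% had the same sign in those pools. This argues against the code 4 pools as the source, but cannot decide on brightness. Within code 4 the morula arrays were also the brighter ones. Their median raw clone intensity was 78 against 49 on aRNA and 68 against 29 on PCR arrays. A real difference among stages stays a candidate explanation for the rest.

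A further pattern is the higher morula signal of lcap than of lcao clones, by 0.25 to 0.39 (log2, difference of medians) on the 3 aRNA arrays and by 0.07 to 0.26 on the 3 PCR arrays, where the arrays of the other stages gave -0.13 to 0.01. A difference in brightness between the sets is argued against, since among clones matched on mean intensity the lcap minus lcao difference in the change from 4-cell to morula was 0.26 (log2), as over all clones. It was not carried by a few plates (96% of lcap plates, 24 of 25, lay above the median of lcao plates) or by a region of the filter (positive in 16 of 16 blocks), and under other normalizations it was at least 0.26 on the log2 scale and 0.23 in the series table's own unit. Among clones with no adjacent spot at 4 times their intensity or more it was 0.30, which argues against spread from spots that bright. Among clones called by the F test, 165 lcap and 56 lcao clones were highest in morulae, and 34 lcap and 117 lcao clones were lowest there. Normalized values are relative to the other clones, so a rise of lcap clones cannot be told apart from a fall of lcao clones. A biological difference between the sets in transcripts that peak or dip in morulae may account for it. This is a hypothesis found and tested on the same data, and the meaning of the prefixes is not given in the sources used here.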
